A study of Mus musculus with 6 samples.

How the data were processed

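RNA from 6 bone marrow culture samples of C57BL/6J mice, 3 control and 3 treated with midkine, was sequenced with a forward 3' end kit (QuantSeq) on an Illumina HiSeq from 500 ng of total RNA, per the labels. The mean RNA integrity number over the samples was 8, with a range of 5 to 10, per the labels, and values for single samples are not given in the sources used here. The submitters' processing notes name FastQC 0.11.0, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq and DESeq2, with the genome builds GRCm38 and mm10. The annotation, and the strand setting of the counting, are not given in the sources used here. Each column name matched 1 sample title, and no column was left unmapped.

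The authors deposited a signal table of 14912 gene symbols in 6 libraries, read counts divided by a size factor per library. Whole reads were recovered by dividing each column by the value of 1 read, which was between 0.916 and 1.13 in the 6 columns. All values, 100% of them, were whole multiples within a tolerance of 1e-06 reads. In the column of midkine replicate 3, 1 read is worth 1.00888, close to 1, and 1.63% of its values lie within 0.001 of a whole number, so its values are scaled and not raw counts. Size factors recomputed from the recovered reads by the median-ratio method matched the inverse of the value of 1 read to 4 decimals. There were no rows without a gene name. No molecular identifiers are named in the sources used here, so intervals and floors cover counting error only.

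Groups came from the treatment label, and replicate numbers from the titles. The spread between replicates was larger than counting noise in every pair (chi-square per degree of freedom 2.31 to 10.6, genes with at least 10 reads), so each library counted as 1 replicate. These values sum over genes, so abundant rows weigh heavily and the spread of a typical gene is not given by them. Among such rows, Gm42418, over the nuclear ribosomal RNA repeat, took 5.89% to 11.96% of the reads in control libraries. Correlations of log2 values were 0.984 to 0.987 within a group and 0.930 to 0.947 between groups.

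Genes with a mean normalised value of at least 10 over the 6 libraries were tested with limma 3.58.1 (lmFit and eBayes with a variance trend, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale and understate changes of low genes. Of 14912 genes 11844 entered the test. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, where at least 3 members were measured: 24 of 27 lists were tested and 17 called, 10 higher and 7 lower. With an estimated correlation 4 calls held: plasmacytoid, cell cycle, cholesterol synthesis and immediate early genes. fry, which tests whether the genes of a list move on balance in one direction and does not compare it with other genes, called 21. Adjustment over the list alone used the members of a list only. A gene with 0 reads in a group was given a bound against 3 counts over the group.

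The named genes were, by a rule fixed with the tests, lists and alternatives before the data were examined, the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap, up to 4 called members per list with the smallest p, and a set of midkine and dendritic cell genes. Predicted genes were passed over and counted (261 of all calls). Some genes that this rule selects are not reported here. A list without a called member gave up to 2 of its measured members. Positions are from the GENCODE vM21 annotation of GRCm38, in which 14852 of 14912 symbols (99.6%) were found. Exons of 8 of the 118 named genes overlapped a tested gene on the other strand and 4 one on the same strand. Genes with near-identical copies could have had reads split or lost, which the counting settings decide.

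The alternatives were pseudocounts of 0.5 and 5, other filters on the mean, rescaling with TMM factors, quantile normalization, no variance trend, a block for the replicate number, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, an adjusted p under 0.1, and leaving out each library. Scaling to total counts, with and without 3 ribosomal RNA rows, was added after seeing the data. edgeR called 5157 genes, of which 5011 were also called by limma. The test was checked on simulated data for midkine against control with 11721 genes, where limma recovered 40 of 66 genes changed 1.5-fold, 56 of 66 changed 2-fold and 63 of 63 changed 4-fold, with 6 false calls (3.64% of calls). In simulated lists of 20 genes, 1 of 200 unshifted lists had a p under 0.05. Genes were simulated independently of one another, so this check does not cover correlation between the genes of a list. Far fewer genes were changed in the simulation than were called in the data. Figures and tables used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.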

Results

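Gene expression was measured by 3' end sequencing in bone marrow cultures of C57BL/6J mice grown with FLT3 ligand, the growth factor that drives dendritic cell development, at 50 ng/ml. The medium with FLT3 ligand was renewed on day 7. During the last 2 days, 3 samples received recombinant human midkine, a heparin-binding growth factor, at 10 ng/ml and 3 control samples received none. The comparison addresses how midkine alters gene expression in dendritic cell cultures. Control libraries held 5089338 to 5532055 reads and midkine libraries 5685055 to 6453768, with 14649 to 14737 genes seen per library. The labels do not say whether the replicates were separate mice or separate cultures, so p-values measure the spread between these samples, which may be technical.

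With midkine, the lists of plasmacytoid dendritic cell (median log2 fold change -1.84), interferon-response (-1.52), cell cycle (-0.97), cholesterol synthesis (-0.79) and type 1 conventional dendritic cell genes (-0.72) were lower. The lists of stromal (1.16), immediate early (0.77), inflammatory cytokine (0.74), stress (0.64), dendritic cell maturation (0.60) and glycolysis genes (0.47) were higher. Of these calls, the plasmacytoid, cell cycle, cholesterol and immediate early ones held in camera with an estimated correlation. The others did not: adjusted p = 0.126 with an estimated correlation for interferon, 0.160 for type 1 cells, 0.169 for stroma, 0.0547 for inflammatory cytokines, 0.0842 for stress, 0.120 for maturation and 0.0766 for glycolysis. Of 11844 genes tested with limma, 2481 were higher and 2578 lower with midkine, and 6785 were not called. At least 2-fold changes were found for 737 higher and 455 lower genes. The libraries separated by treatment along the first principal component, which held 72.0% of the variance. All 3 midkine values lay on one side of all 3 control values for 51.3% of the genes, where chance gives 10%. The split of calls depended on the scaling between libraries. Scaling to total counts, an alternative chosen after seeing the data, gave 1283 higher and 4817 lower genes (21.0% higher, against 49.0%) and shifted the median of all genes to -0.26. Leaving mitochondrial and nuclear ribosomal RNA out of the totals gave 2023 higher and 3178 lower genes (38.9% higher).

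**Figure D1:**
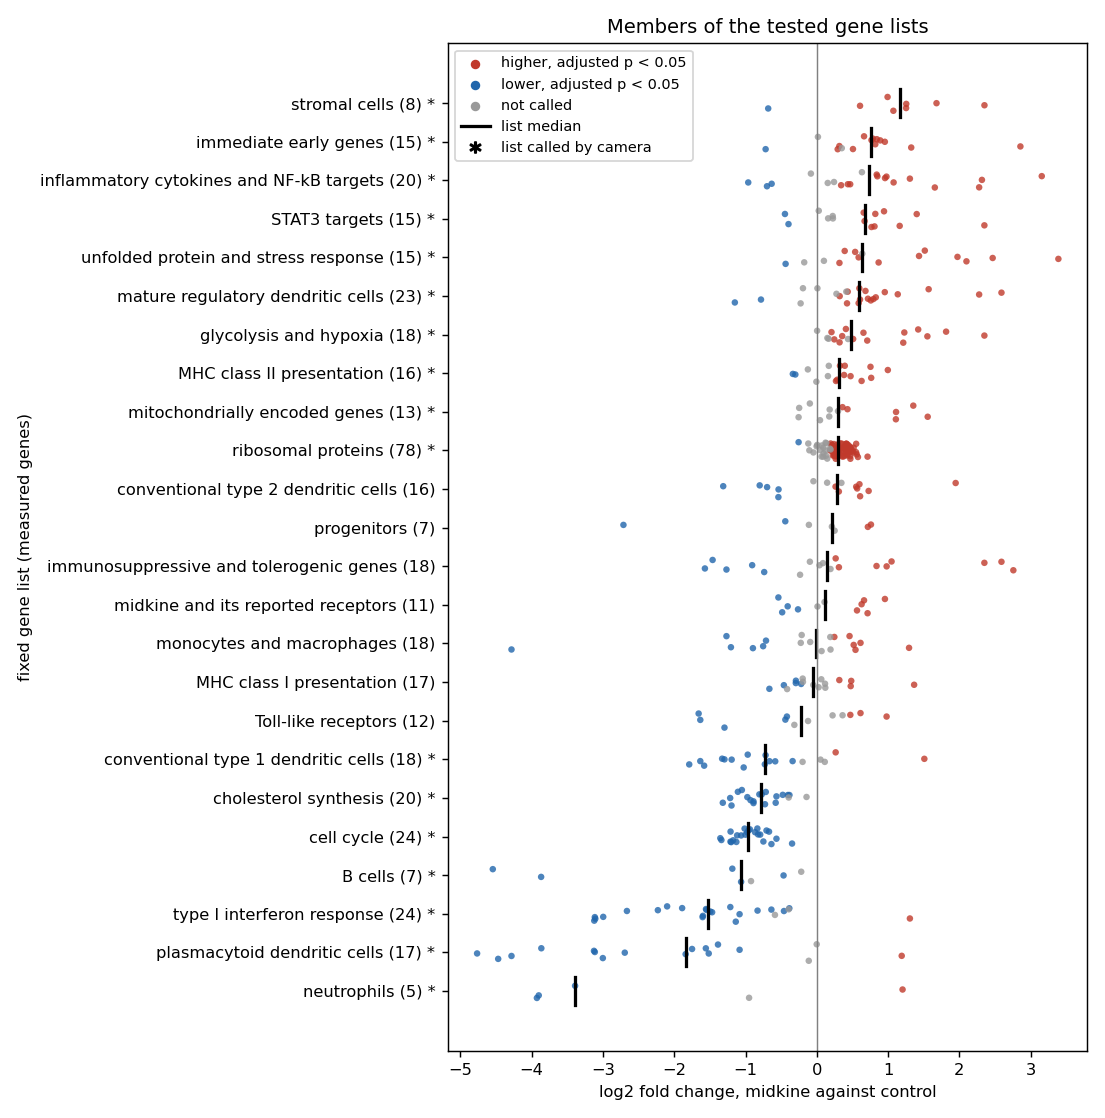
Log2 fold changes (midkine against control, x axis) of the measured members of each tested gene list, with the list name and its number of measured genes on the y axis; each point is a gene, coloured by its limma call at an adjusted p under 0.05, the black bar is the list median, and an asterisk marks lists called by camera. The plasmacytoid list has a median of -1.84 and the stromal list a median of 1.16; Vpreb1, without midkine reads, is drawn at its fitted value.

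Most markers of plasmacytoid dendritic cells, the main producers of type I interferon, fell. Of 17 measured markers 14 fell and 1 rose, with the same counts adjusted over the list alone, and the list median was -1.84 (camera adjusted p = 2.8e-15; adjusted p = 0.0214 with an estimated correlation). Siglech, a surface lectin of these cells, fell from 816 ± 36.3 to 102 ± 18.3 normalised read counts (mean ± SD, n = 3 each; 8.01-fold lower, SE 0.11 on the log2 scale, limma adjusted p = 1.0e-16). Siglech lies on chromosome 7 from 55768178 to 55778925 of GRCm38. Ccr9, a chemokine receptor gene on chromosome 9 from 123678439 to 123784330, fell from 571 ± 41.8 to 20.4 ± 4.82, the deepest change of the named genes with midkine reads in all libraries (log2 fold change -4.77). Tcf4, the transcription factor that specifies the lineage, had a log2 fold change of -1.56. Ly6d (-2.69), Upb1 (-4.47) and Pacsin1 (-3.86) fell further. Cd209d ran against the rest with a log2 fold change of 1.19, and Ptprs (-0.11) and Cox6a2 (-0.0016) were not called. Here and below, members named for running against their list were chosen after their values were seen. Beside these falls, the stromal list median was 1.16 and the mitochondrial ribosomal RNA share was 9.63% in control and 19.8% in midkine libraries.

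Interferon-stimulated genes were also lower, and Irf7 and Bst2 among them are in the plasmacytoid list too. Of 24 measured genes 21 fell and 1 rose, with the same counts adjusted over the list alone, at a median of -1.52 (camera adjusted p = 7.3e-12; adjusted p = 0.126 with an estimated correlation). Irf7, a transcription factor that amplifies interferon production, fell from 177 ± 45.3 to 19.3 ± 1.89 normalised read counts (log2 fold change -3.11, limma adjusted p = 8.6e-13), and its exons overlap those of Phrf1 on the other strand. Rtp4 fell 7.98-fold, and the antiviral gene Mx1 (-1.47) and Trim30a (-1.21), from a family of similar copies, fell on the log2 scale. The exception was Ifi44 at 1.31. The Toll-like receptor list was not called (median -0.22, 3 higher and 5 lower of 12; camera adjusted p = 0.187); adjusted over the list alone, 4 were higher and 5 lower. Scaling to total counts gave 1 higher and 6 lower, at a median of -0.47. Among its nucleic acid sensors Tlr7 (-1.66) and Tlr3 (-1.30) fell and Tlr13 (0.47) rose. Tlr11 (-1.63), a sensor of profilin, fell, and Tlr6 (0.98) and the adaptor gene Ticam1 (0.61) rose. Tlr3 and Tlr11 are also in the list of type 1 conventional dendritic cells. Unc93b1, which carries endosomal Toll-like receptors, had a log2 fold change of -0.44. Beside the interferon genes the stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63% in control libraries.

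Type 1 conventional dendritic cell markers fell, whereas type 2 markers went both ways. Of 18 type 1 markers 13 fell and 2 rose, as they did adjusted over the list alone (median -0.72; camera adjusted p = 3.5e-07; adjusted p = 0.160 with an estimated correlation). Xcr1, the chemokine receptor that marks these cells, fell from 1876 ± 271 to 635 ± 161 normalised read counts (log2 fold change -1.58, SE 0.12, limma adjusted p = 8.5e-11). Clec9a, a receptor for dead cells, fell (-1.03) and shares exonic sequence with Clec1b. Naaa (-1.79), Irf8 (-0.73), the transcription factor needed for these cells, and Ifi205 (-1.19), from a family of similar copies, fell too. Itgae at 1.51 and Id2 at 0.26 rose. Batf3, a partner of Irf8, had overlapping groups and a log2 fold change of -0.34 (limma adjusted p = 0.0372). The log2 fold change of Batf3 became -0.26 without control replicate 1, -0.25 without control replicate 3, -0.30 without midkine replicate 1 and -0.29 without midkine replicate 3, none of them called, and its adjusted p over 18 alternatives ranged from 0.000586 to 0.190. Among 16 type 2 markers 8 rose and 5 fell, or 9 and 5 adjusted over the list alone (median 0.29; camera adjusted p = 0.670, with fry placing the list in the opposite direction). The split became 3 higher and 6 lower with scaling to total counts, at a median of 0.03, or 0.29 relative to all genes. Itgam had a log2 fold change of 0.60 and Sirpa, a type 2 surface marker, of 0.26, or 0.0044 and not called with scaling to total counts. Cd7 (-1.31), Clec12a (-0.70), Klf4 (-0.54) and Notch2 (-0.54) fell. Irf4, a transcription factor of type 2 cells, was at 66.2 ± 11.5 in control and 72.9 ± 9.15 in midkine cultures (log2 fold change 0.14, limma adjusted p = 0.529). Flt3, the FLT3 ligand receptor, was at 634 ± 34.9 and 586 ± 12.8 (log2 fold change -0.11, limma adjusted p = 0.298), and was called at -0.37 with scaling to total counts. Itgax, which encodes CD11c, rose by 0.83 on the log2 scale. As the type 1 markers fell, the stromal median was 1.16 and mitochondrial ribosomal RNA took 19.8% of the reads, against 9.63%.

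**Figure D2:**
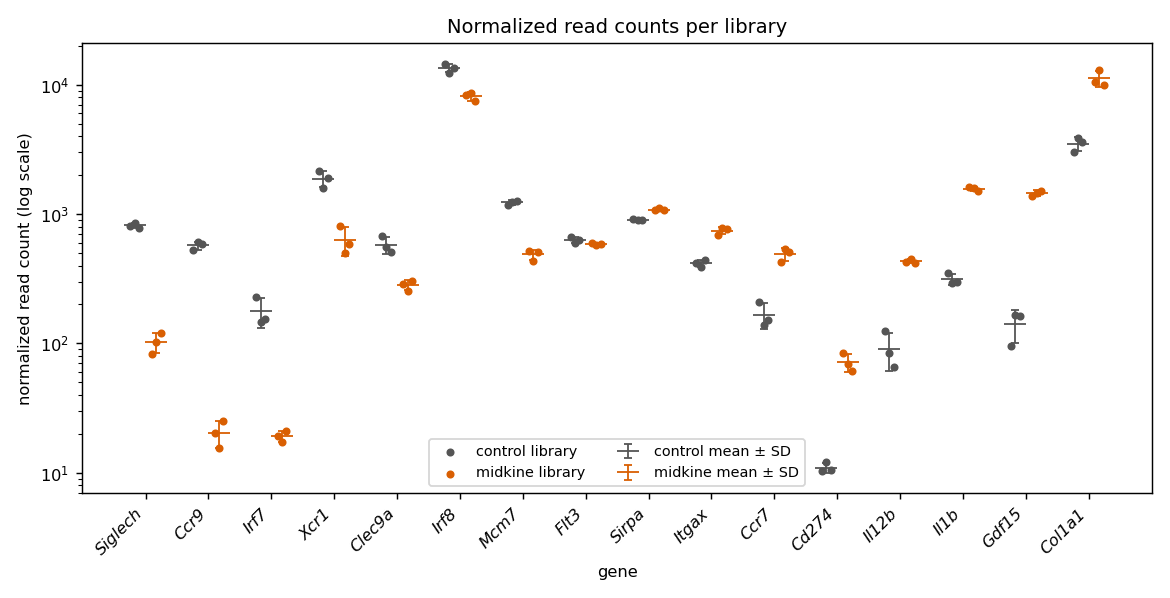
Normalised read counts (log scale, y axis) of 16 named genes (x axis) in the 3 control and 3 midkine libraries; points are libraries and bars are the mean ± SD. Siglech and Ccr9 lie lower, and Cd274 and Il12b higher, in every midkine library than in every control library, whereas Flt3 differs by a log2 fold change of -0.11 that was not called.

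Most genes of mature regulatory dendritic cells were higher with midkine. Of 23 measured genes 16 rose and 2 fell, or 17 and 2 adjusted over the list alone (median 0.60; camera adjusted p = 8.9e-05; adjusted p = 0.120 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose from 10.98 ± 0.995 to 71.6 ± 11.7 normalised read counts (log2 fold change 2.59, SE 0.24, limma adjusted p = 2.1e-09). Cd274 lies on chromosome 19 from 29367455 to 29388095. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose from 166 ± 37.6 to 489 ± 55.7 (log2 fold change 1.57). Il12b, the shared subunit of interleukins 12 and 23, rose by 2.28 and the costimulatory gene Cd86 by 0.61. Marcks (-0.78) and Marcksl1 (-1.15) fell. Ccl22 (0.41), Birc3 (0.28), Cd80 (0.0084), Tnfrsf4 (-0.19) and Cd40 (-0.23) were not called over all genes. Inflammatory cytokine and NF-kB target genes rose as well, with 13 of 20 higher and 3 lower, as adjusted over the list alone (median 0.74; camera adjusted p = 8.9e-05; adjusted p = 0.0547 with an estimated correlation). Il1b rose from 314 ± 30.7 to 1564 ± 52.9, a log2 fold change of 2.32, and Il12b is also in this list. Il12a, which encodes the other subunit of interleukin 12, was below the minimum value, with 31 control and 9 midkine reads. Il6 (4 and 29 reads) and Il1a (2 and 3) were also below it. The chemokines Ccl3 and Ccl4 rose by 1.66 and 1.31, while Nfkb1 (-0.63), Icam1 (-0.96) and Ccl2 (-0.70) fell. The stromal list (median 1.16) moved the same way as both lists, and the mitochondrial ribosomal RNA share was 19.8%, against 9.63%.

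Antigen presentation genes moved by less. In the MHC class II list 10 of 16 genes rose and 2 fell, as adjusted over the list alone (median 0.31; camera adjusted p = 0.00285; adjusted p = 0.112 with an estimated correlation). H2-DMb2 rose by 1.00, Ctsl by 0.76, Ctss by 0.75 and Ifi30 by 0.63, the last 3 encoding lysosomal proteins that process antigen, while March1 (-0.34) and H2-DMa (-0.30) fell. The 4 others, Cd74 (0.17), H2-Aa (0.16), Ciita (-0.0065) and H2-DMb1 (-0.13), a relative of H2-DMb2, were not called. With scaling to total counts 4 class II genes were higher and 4 lower at a median of 0.05, or 0.31 relative to all genes, and the list was no longer called (camera adjusted p = 0.0586). The class II rise went with a stromal median of 1.16 and a mitochondrial ribosomal RNA share of 19.8%, against 9.63%. The MHC class I list was not called, with 4 of 17 genes higher and 5 lower, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.983). With scaling to total counts 2 were higher and 9 lower, at a median of -0.31, or -0.04 relative to all genes. Its median of -0.05 and the test lay below 0 and its mean of 0.01 above. H2-Q7 had a log2 fold change of 1.36, H2-K1 of 0.48 (0.22 and not called with scaling to total counts, 0.19 and not called with quantile normalization), the chaperone gene Calr of 0.48 and the immunoproteasome gene Psmb10 of -0.46; H2-Q7 and H2-K1 belong to families of near-identical copies between which reads could be split.

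Immediate early genes, induced within minutes of a stimulus, were higher. Of 15 measured, 12 rose and Fosb alone fell (by 0.72), as adjusted over the list alone (median 0.77; camera adjusted p = 1.4e-07; adjusted p = 0.0408 with an estimated correlation). Ier3 rose from 407 ± 41.5 to 2941 ± 17.2 normalised read counts (log2 fold change 2.86, SE 0.08, limma adjusted p = 1.5e-18). Egr1 rose by 1.32, Jun by 0.95 and Zfp36 by 0.89. Targets of STAT3, a transcription factor activated by cytokines, rose in 9 of 15 cases and fell for Myc (-0.45) and Ccnd1 (-0.40); adjusted over the list alone, 10 rose and 2 fell (median 0.67; camera adjusted p = 1.6e-05; adjusted p = 0.111 with an estimated correlation). Il4ra rose by 1.16, Junb by 0.82 and Fos by 0.77. Junb and Fos are also in the immediate early list, and the STAT3 target Vegfa, given below, is in the hypoxia list. The rises of these lists are therefore not separate evidence. Stat3 itself (0.22), Bcl6 (0.16), Batf (0.23) and Mcl1 (0.03) were not called over all genes. Beside these genes the stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63% in control libraries.

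Stress and hypoxia genes were higher with midkine. In the unfolded protein and stress list 11 of 15 rose and Dnajb1 fell by 0.44, as adjusted over the list alone (median 0.64; camera adjusted p = 1.9e-07; adjusted p = 0.0842 with an estimated correlation). Gdf15, a stress-induced cytokine gene on chromosome 8 from 70629393 to 70632456, rose from 142 ± 40.1 to 1449 ± 70.8 normalised read counts (log2 fold change 3.39, SE 0.14, limma adjusted p = 3.2e-16). Trib3 rose by 2.47, Ddit3, whose exons overlap those of Mars on the other strand, by 2.10 and Atf3 by 1.43. Glycolysis and hypoxia genes rose in 14 of 18 cases and none fell, as adjusted over the list alone (median 0.47; camera adjusted p = 1.3e-07; adjusted p = 0.0766 with an estimated correlation). Vegfa, the hypoxia-induced angiogenic factor, rose from 143 ± 17.9 to 728 ± 40.9 (log2 fold change 2.35). The lactate transporter Slc16a3 rose by 1.81, Bnip3 by 1.42 and the glycolytic enzyme gene Aldoa by 1.23. With scaling to total counts the hypoxia median was 0.22, with 8 genes higher and 1 lower. Stromal markers (median 1.16) and mitochondrial ribosomal RNA (19.8% of reads, against 9.63%) were higher beside both lists.

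Proliferation genes fell without exception in the measured list. All 24 cell cycle genes were lower, also adjusted over the list alone (median -0.97; camera adjusted p = 2.8e-15; adjusted p = 0.0332 with an estimated correlation). Mcm7, a subunit of the replicative helicase with exons overlapping Ap4m1 and Cops6 on the other strand, fell from 1229 ± 47.0 to 487 ± 44.9 normalised read counts (log2 fold change -1.34). Mcm5 (-1.17), Mcm6 (-1.06) and Birc5 (-0.96), which encodes survivin, also fell. Cholesterol synthesis genes fell in 18 of 20 cases, or 19 adjusted over the list alone, and none rose (median -0.79; camera adjusted p = 2.2e-10; adjusted p = 0.0408 with an estimated correlation). Fdps (-1.11), which encodes farnesyl diphosphate synthase, and Cyp51 (-0.89), a sterol demethylase gene, fell. Cyp51 overlaps Akap9 on the other strand. Ribosomal protein genes were slightly higher, with 59 of 78 rising and 1 falling, or 60 and 1 adjusted over the list alone (median 0.29; camera adjusted p = 2.5e-11; adjusted p = 0.137 with an estimated correlation). Rps19 rose by 0.71, Rpl12 by 0.58, Rpl36a and Rpl24 by 0.55, and processed copies of such genes could share their reads. With scaling to total counts 12 rose and 6 fell, at a median of 0.04, or 0.30 relative to all genes, and quantile normalization gave 30 and 4 at a median of 0.08. Where the cell cycle and cholesterol genes were lower and the ribosomal protein genes higher, the stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63%.

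Markers of other cell types also moved. Of 8 stromal markers 7 rose and Cxcl12 fell by 0.68, as adjusted over the list alone (median 1.16; camera adjusted p = 1.3e-05; adjusted p = 0.169 with an estimated correlation). Postn, a matrix protein gene, rose from 370 ± 36.2 to 1890 ± 83.3 normalised read counts (log2 fold change 2.35, SE 0.09, limma adjusted p = 5.9e-17). Col1a1, the type I collagen gene on chromosome 11 from 94936224 to 94953042, rose from 3485 ± 435 to 11177 ± 1633, and Col1a2 and Col3a1 rose by 1.25 each on the log2 scale. Of 5 neutrophil markers 3 fell and Mmp8 rose by 1.20, with 4 lower adjusted over the list alone (median -3.39; camera adjusted p = 0.00264; adjusted p = 0.0977 with an estimated correlation). The alarmins S100a8 (-3.93) and S100a9 (-3.90) and the granule gene Ngp (-3.39) fell. Only 5 of the 16 neutrophil markers in the list reached the minimum value. Below it, Ltf (42 control and 4 midkine reads), Camp (34 and 11) and Lcn2 (23 and 4) were lower. Csf3r (15 and 41) and Prtn3 (24 and 34), also below it, were higher. Of 7 B cell markers 5 fell and none rose, or 6 adjusted over the list alone (camera adjusted p = 6.2e-04; adjusted p = 0.120 with an estimated correlation). Vpreb1, the surrogate light chain gene on chromosome 16 from 16868403 to 16870843, had 85 control reads and 0 midkine reads and was at least 27.4-fold lower against a floor of 3 counts over the group (log2 fold change -4.55, or -5.27 without control replicate 1). Its exons overlap those of Top3b on the other strand. Rag1, the recombinase gene, had 63 control reads and 2 midkine reads, both in midkine replicate 3, so no finite ratio is left without that library. With all libraries the ratio was 30.3 with a 95% counting interval of 8.04 to 255. The gene shares exonic sequence with a predicted gene. Ighm (-1.19) and Blnk (-1.06) fell, and Pax5 (-0.92) and Cd79b (-0.22) were not called over all genes. The B cell median was -1.06, also with Vpreb1 at its bound. The mitochondrial ribosomal RNA share beside these cell type markers was 19.8%, against 9.63%.

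Monocyte and macrophage markers went both ways, with 6 of 18 higher and 6 lower, as adjusted over the list alone (median -0.01; camera adjusted p = 0.584). With scaling to total counts 2 were higher and 9 lower, at a median of -0.27, or -0.01 relative to all genes. Ly6c2, a monocyte marker with a near-identical neighbour and also in the plasmacytoid list, fell (-4.28), as did Mrc1 (-1.27) and C1qa (-1.21). Progenitor markers were not called as a list, with 2 of 7 higher and 2 lower, as adjusted over the list alone (camera adjusted p = 0.716). Their median of 0.21 lay above 0 and became -0.05 with scaling to total counts (0 higher and 3 lower), and their mean of -0.19 and the test lay below 0. Myb (-2.71) and Kit (-0.44), also the only measured mast cell marker, fell. Cd34 had a log2 fold change of 0.76, or 0.51 and not called with scaling to total counts. The log2 fold change of Hoxa9 was 0.72 (limma adjusted p = 0.0112), and was 0.47 without control replicate 1 and 0.64 without midkine replicate 1, neither called; its adjusted p over 17 alternatives ranged from 0.00363 to 0.0975. The log2 fold change of Cd5, the only measured T and NK cell marker, was 0.64 and not called (12.4 ± 1.92 and 20.7 ± 8.01; limma adjusted p = 0.121). Without midkine replicate 1 it was 0.90 and called, with an adjusted p over 17 alternatives from 0.0451 to 0.477. No erythroid marker reached the minimum value.

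Immunosuppressive and tolerogenic genes split, with 8 of 18 higher and 5 lower, as adjusted over the list alone (median 0.14, and -0.12 with 6 higher and 7 lower with scaling to total counts; camera adjusted p = 0.138). Gpnmb, a glycoprotein of macrophages and dendritic cells, rose from 1385 ± 361 to 9144 ± 638 normalised read counts (log2 fold change 2.76, limma adjusted p = 1.6e-15). Vegfa rose by 2.35, while Il1rn, the interleukin 1 receptor antagonist gene, fell (-1.57), as did Mrc1 (-1.27). Mdk, the mouse midkine gene itself, rose from 16.7 ± 5.41 to 32.9 ± 6.87 (log2 fold change 0.96, SE 0.28, limma adjusted p = 0.00745). The list of midkine and its reported receptors was not called, with 5 of 11 higher and 4 lower, as adjusted over the list alone (median 0.11, and -0.15 with 5 higher and 5 lower with scaling to total counts; camera adjusted p = 0.505). The receptor Lrp1 rose from 505 ± 85.5 to 792 ± 42.0 (log2 fold change 0.66, limma adjusted p = 8.5e-06). Itga6 and Itgb1 rose by 0.63 and 0.56, and Notch2 fell (-0.54). The stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63%, and which cells carried these changes was not tested. Ptprz1 and Alk were not analysed here.

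Mitochondrial ribosomal RNA took 9.63% ± 0.27 of the reads in control and 19.8% ± 1.49 in midkine libraries (mean ± SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The 2 genes, mt-Rnr1 and mt-Rnr2, had log2 fold changes of 1.11 and 1.35. Other mitochondrial reads were 0.810% ± 0.0819 and 0.747% ± 0.0692. In the list of mitochondrially encoded genes 6 of 13 rose and none fell, or 7 and 1 adjusted over the list alone (median 0.30; camera adjusted p = 0.00285; adjusted p = 0.324 with an estimated correlation), and with quantile normalization the list was not called (adjusted p = 0.279). Quantile normalization gave 5 higher and 3 lower genes, and scaling to total counts 4 and 4 at a median of 0.04, or 0.30 relative to all genes. mt-Co1 and mt-Nd6 rose by 1.11 and 1.56, and mt-Nd6 overlaps mt-Nd5 on the other strand. Gm42418, a transcript over the nuclear ribosomal RNA repeat, took 9.30% ± 3.10 and 8.70% ± 1.08 of the reads.

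The 12 named genes with the greatest rises, passing over 2 predicted genes, had log2 fold changes of 2.97 to 3.49. Besides Gdf15 they included Lgr6, a receptor for R-spondins (3.49), the cell cycle inhibitor Cdkn1c (3.46), Hic1 (3.36), Lrrc32, which anchors latent TGF-beta (3.23), the cytokine Lif (3.22), the prostaglandin synthase Ptgs2 (3.16), endothelin 1, Edn1 (3.09), Aif1l (3.06), the lipase Mgll (3.00) and Tspoap1 (2.97). Edn1, on chromosome 13 from 42301476 to 42307990, rose from 52.8 ± 4.85 to 455 ± 14.1 normalised read counts (limma adjusted p = 1.5e-16). Beside these 12 rises the stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63%. Which cells carried the rises was not tested. Lif and Ptgs2 were seen with 4 and 5 reads in the 3 control libraries. Those with the greatest falls, passing over 1 predicted gene, added Chil5 (-4.34), Smim5 (-4.19), Fcrla, a B cell protein (-3.96), and Havcr1 (-3.91, or -2.90 without midkine replicate 3, where it had no reads) to the genes above, and Chil5 belongs to a family of similar copies.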

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

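Scaling to total counts, with and without the ribosomal RNA rows, was chosen after seeing the data; the other alternatives were planned. No call reversed under any alternative. Scaling to total counts gave 1283 higher and 4817 lower genes, requiring at least 2-fold gave 737 and 455, and 4 lists held with an estimated correlation; the first follows from a shift of all medians, the second from a stricter threshold. In the other 18 alternatives, counts were 1899 to 2891 higher and 2021 to 3178 lower. Leaving out 1 library gave 2139 to 2287 higher and 2136 to 2344 lower genes and 17 lists each time. The replicate block gave 2519 higher and 2641 lower genes and 17 lists; same-number correlations of -0.01, 0.029 and -0.058 do not pair the samples, and not every sample correlated best with its own number. Of the 118 named genes, 110 kept their call in every alternative run, though Irf4, never called, changed sign without control replicate 2 and with scaling to total counts, and 8 changed a call in at least 1: Batf3, Cd34, Cd5, Flt3, H2-K1, Hoxa9, mt-Rnr1 and Sirpa, and the cause was not tested. The log2 fold change of mt-Rnr1 is 0 under quantile normalization, since it holds the same rank in every library. fry called 4 more lists. Of the 17 called lists, the MHC class II list was lost with scaling to total counts (camera adjusted p = 0.0586) and the mitochondrial list with quantile normalization (camera adjusted p = 0.279). The other 15 stayed at an adjusted p of at most 0.0227 in every alternative in which they were tested, except the estimated correlation. With a filter on a mean value of at least 50, the neutrophil list kept too few members to be tested. Depth limits genes with few reads: Lif and Ptgs2 rest on 4 and 5 control reads.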

Other observations

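The tests of stromal share, plasmacytoid share, dilution by stromal RNA, mitochondrial messenger RNA and RNA without poly(A) tails, and the fibroblast, TGF-beta, iron and lysosome lists, were chosen after results were seen; the TGF-beta, library scaling and split tests were written before their values were seen.

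Further TGF-beta target genes were higher beside the stromal markers. Of 20 further TGF-beta targets 17 rose and 2 fell, at a median of 1.04 (camera adjusted p = 3.3e-11; adjusted p = 0.145 with an estimated correlation), and Tgfbi and Tgfbr1 were the ones that fell. Tagln, which encodes transgelin, rose by 2.28, Acta2, which encodes smooth muscle actin, by 2.11 and Thbs1 by 1.96 on the log2 scale. Acta2 rose from 2508 ± 213 to 10770 ± 570 normalised read counts. Of 37 wider fibroblast markers 28 rose and 4 fell (median 0.77; camera adjusted p = 1.7e-11; adjusted p = 0.145 with an estimated correlation), with Fbln2 at 2.07 and Sfrp1 at -1.26; 8 of these markers are also in the fixed stromal list. Scaling to total counts gave 14 higher and 2 lower TGF-beta targets (median 0.78) and 22 higher and 6 lower fibroblast markers (median 0.51). Beside both lists, mitochondrial ribosomal RNA took 9.63% of the reads in control and 19.8% in midkine libraries.

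The iron list was not called (6 of 15 higher and 3 lower, median -0.10; camera adjusted p = 0.150; adjusted p = 0.232 with an estimated correlation), and scaling to total counts gave 6 higher and 7 lower. Of its genes, picked after their values were seen, Fth1, the ferritin heavy chain gene on chromosome 19, rose from 5582 ± 156 to 22090 ± 3171 normalised read counts and Ftl1 by 1.42 on the log2 scale, while Tfrc, the transferrin receptor gene, fell by 1.43. Of 35 lysosome genes 18 rose and 4 fell (median 0.25; camera adjusted p = 0.00108; adjusted p = 0.174 with an estimated correlation). With scaling to total counts 11 were higher and 11 lower, at a median of -0.00477, or 0.26 relative to all genes (camera adjusted p = 0.0155). The stromal median was 1.16 and the mitochondrial ribosomal RNA share 19.8%, against 9.63%. Atp6v0d2 rose by 2.28, Ctsd by 1.40 and Lipa by 1.23, whereas Gusb (-0.95) and Man2b1 (-0.97) fell.

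Stromal genes were higher with midkine. A larger share of stromal cells as the whole cause would raise fibroblast markers alike if only these cells made them and their makeup stayed the same. Of 34 markers with a mean of at least 50, 22 (64.7%) lay more than 3 SE from their median of 0.87. Of the 34, 27 rose and 4 fell, the latter including Igfbp4 and Cxcl12. Neither condition was tested, so this spread cannot decide between a larger share and changed expression. A TGF-beta-type response in addition may contribute. The difference of medians, further TGF-beta targets minus wider fibroblast markers, was 0.271 (bootstrap interval -0.27 to 0.91, permutation p of 0.301). Such a response and a general rise of fibroblast genes therefore cannot be told apart. The permutation here and the bootstrap intervals here and below resample genes and not libraries, so they do not measure the spread between samples. A larger share of stromal cells, a change in expression within them, or both, stay open, as does which cells midkine acted on.

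Plasmacytoid, interferon and type 1 conventional dendritic cell genes were lower, and library scaling leaves the interferon median at -1.52 or lower in every other scaling run. Dilution by stromal RNA as the whole cause would lower dendritic cell genes by the same factor, but the type 2 median exceeded the type 1 median by 1.01 (bootstrap interval 0.19 to 1.58) and the plasmacytoid median by 2.13 (1.30 to 3.56); some dilution stays open, with a bootstrap interval of -0.54 to 0.57 for the type 2 median itself and the MHC class II median at 0.05 with scaling to total counts. Whether a smaller share of plasmacytoid cells carries the lower interferon genes could not be settled. The deepest interferon fall (-3.12) was shallower than that of the deepest plasmacytoid marker by 1.64 log2 units. It was deeper than the plasmacytoid median (-1.84), so the outcome depends on the marker taken. Irf7 and Bst2 are in both lists. Loss of these cells and lower interferon signalling cannot be told apart. Whether plasmacytoid and type 1 cells were fewer or expressed less stays open and was not tested.

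Mitochondrial ribosomal RNA was higher with midkine. More mitochondrial RNA of every kind is argued against: the 11 messenger RNAs had a median of 0.180 (bootstrap interval -0.10 to 0.43), against 1.11 and 1.35 for the ribosomal RNAs, and 9 lay more than 0.5 below the lower of these. They ranged from -0.26 to 1.56, and mt-Co1 (1.11) and mt-Nd6 (1.56) rose about as much as the ribosomal RNAs. More capture of RNA without a poly(A) tail would raise other such RNAs. The 12 compared, Gm42418, Rn7sk and 10 snoRNAs, most with few reads, had a median of -0.311. Gm42418 was at 0.22 (interval -0.36 to 0.79). None of the 12 is mitochondrial, so more capture of mitochondrial RNAs such as mt-Nd6 stays open. Differences in RNA quality between groups were not tested, because integrity values per sample are not given in the sources used here, and a biological change in mitochondrial ribosomal RNA may equally contribute.

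The real grouping gave 5059 called genes and the highest of the other splits gave 0; with 10 splits (1 as large, the real one included), they are too few for a share under 0.05.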
